A study of Arabidopsis thaliana with 6 samples.

How the data were processed

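Poly(A) RNA from whole Arabidopsis thaliana Col-0 seedlings was sequenced from strand-specific libraries, per the labels' protocols, in 3 control libraries and 3 libraries exposed to 15 µM DMMTA for 6 h at an age of 6 days. Groups were taken from the labels, which call the samples biological replicates. The deposited tables hold 1 row per coding sequence with RPKM, FPKM and TPM, per the file headers. The headers name the RPKM column and do not define it, and it was taken in its usual meaning, reads scaled by length and by library size, as computed by the authors. The FPKM values were also computed by the authors, per the file headers, and served as an alternative. The deposited TPM column served only as a check. The submitters' processing notes name DESeq2, with no version and no role. The aligner, the counting tool, the genome build and the filters are not given in the sources used here.

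Each table has 48350 rows. In 1884 rows (3.90%), those whose description holds a comma or semicolon, the cells were displaced (1678 rows) or emptied (206 rows), and these rows were left out. The 46466 rows used belong to 26551 loci, of which 26444 matched the annotation of TAIR10.1. That annotation was used only for names, descriptions, coding length and GC content, and no coordinates are printed because the build of the files is not named. RPKM was summed over the coding sequences of a locus (10267 loci had several), since reads appeared to be divided between identical sequences, and rescaled to the same total in every library, the usual total of TPM. The result is called TPM here. Near-identical paralogs may share reads in the same way, so members of such families are uncertain. The deposited TPM was summed and rescaled over the same rows for the check, and where it was above 5 the difference was at most 1.06%. Before rescaling, the rows used held 97.6% to 97.7% of the deposited TPM total.

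The files hold no counts. Depth was estimated from the steps between low RPKM values and from displaced rows, at about 66100000 to 134000000 reads per library. Between 82.0% and 90.5% of low values lay within 0.2 read of a whole number. Organelle loci held 0.838% to 1.44% of the control libraries and 0.917% to 1.75% of the DMMTA libraries, and none of the 118 tested was called by limma, while 7506 of all 18813 loci had an unadjusted p under 0.05.

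The design fixed before the data were examined named a count test, with limma on log2(value + 0.5) should the files hold no counts, and the latter was used. Loci with at least 1 TPM in at least 3 libraries were fitted with limma 3.58.1 (R 4.3.3), with an intensity trend and no covariates, and called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested against other genes with camera at an inter-gene correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the 28 lists tested. The 29 lists hold 541 members, written before the data were examined. Of these, 22 were dropped because no name that the annotation gives the locus, in most cases only clone names, matched the listed symbol, and 34 had no usable value, many of them because the symbol holds a semicolon, and 485 were used. Families were matched by product description and adjusted separately.

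Genes are named in the text by a rule fixed before the data were examined. It takes the 5 largest rises and 5 largest falls among called genes with a mean log2 level of at least 1 and groups that do not overlap, and from each list the 2 largest called changes in its majority direction and the 1 largest in the other. GSH1, GSH2, PCS1, PCS2, ABCC1, ABCC2 and HAC1 are always named.

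The fit was tested on simulated data for the comparison of DMMTA with control, over 18651 simulated genes that passed the filter. It recovered 11 of 66 genes changed 1.5-fold (16.7%), 40 of 67 changed 2-fold (59.7%) and 61 of 65 changed 4-fold (93.8%), the rest of the 200 seeded genes having failed the filter, and 3.45% of its calls were false. Alternatives were another filter or none, leaving out libraries, the replicate number as a block, stricter thresholds, another scaling, limma-voom on reads rebuilt from RPKM, other pseudocounts (0.1 and 2), FPKM, nuclear loci only, an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9.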

Results

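RNA was sequenced from whole seedlings of Arabidopsis thaliana, accession Col-0, grown in shaken liquid medium for 6 days. The DMMTA group was exposed for 6 h to 15 µM dimethylmonothioarsenate (DMMTA), a methylated arsenic compound in which a sulfur takes the place of an oxygen of dimethylarsenate. The control group received none. Each group held 3 libraries, which the labels call biological replicates. Estimated depth was about 117000000, 134000000 and 72400000 reads in the control libraries and 99500000, 110000000 and 66100000 reads in the DMMTA libraries, worked out from the steps between low values because the files give no counts. These reads are not independent molecules. Levels below are TPM computed from the deposited RPKM values, as mean ± SD over the n = 3 libraries of a group. Folds are ratios of mean TPM. Log2 fold changes are on the log2(TPM + 0.5) scale, which understates changes of low genes. The largest changes are ranked on that scale, which can differ from the order of the folds, and adjusted p-values are from limma with Benjamini-Hochberg adjustment over all genes tested.

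The comparison asks which transcripts differ after 6 h of DMMTA. Of 18813 loci tested, 3273 rose and 1979 fell in DMMTA. Of the called loci, 1165 rose and 610 fell at least 2-fold, and 326 and 114 at least 4-fold. These counts use the log2 fold changes, not the ratios of mean TPM, with the folds as cut-offs that were not themselves tested. The first principal component held 75.1% of the variance and separated the groups, and 46.5% of loci had groups that did not overlap, where chance gives 10%. Without DMMTA replicate 3 the counts were 2076 and 1132, without DMMTA replicate 2 the number that rose was 2181, and without both replicate 3 libraries, the shallowest of each group, the counts were 1843 and 847. Of the calls, 62.3% were higher in DMMTA in the main test, 56.9% with median-of-ratios scaling and 50.8% with limma-voom on rebuilt reads. The median log2 fold change of all genes was 0.04, -0.004 and -0.05 in these fits. The balance of directions therefore depends on the scaling and fit chosen.

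**Figure D1:**
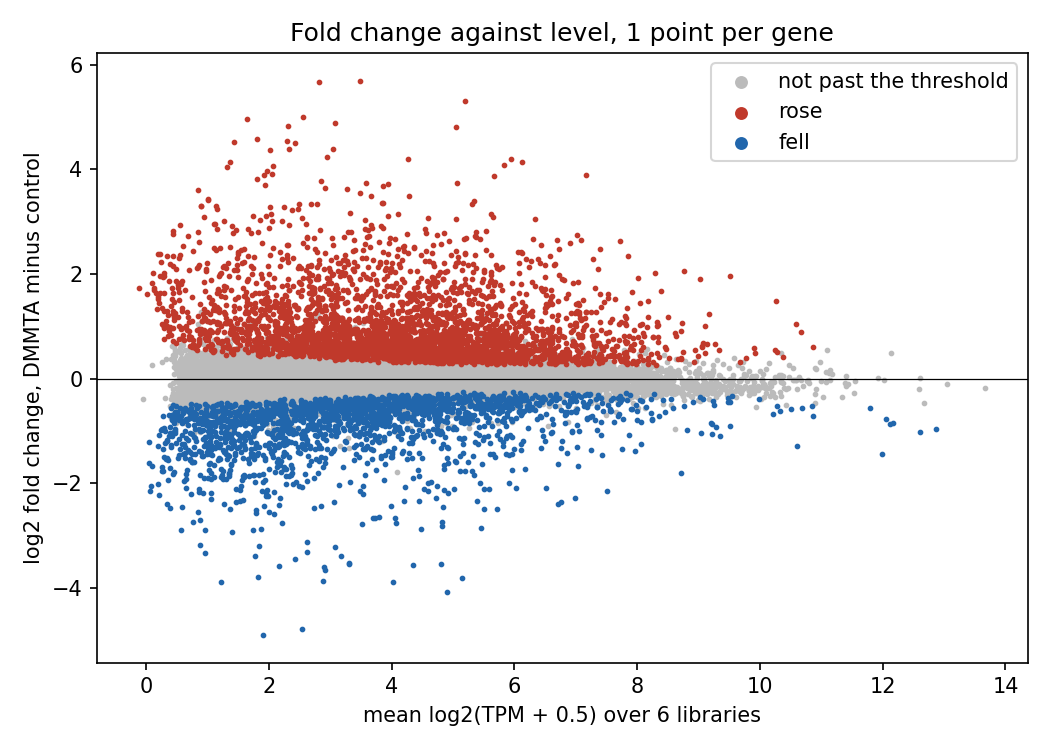
Log2 fold change (DMMTA minus control) against mean log2(TPM + 0.5) over the 6 libraries, 1 point per locus. Red points are the 3273 loci that rose, blue points the 1979 that fell and grey points those not past the adjusted p threshold of 0.05.

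Among called loci with a mean log2 level of at least 1 and groups that did not overlap, the largest rise in log2 fold change was that of SMR7 (AT3G27630), a cyclin-dependent kinase inhibitor of the SIAMESE-RELATED family, from 1.06 ± 0.0819 to 80.5 ± 5.33 TPM (log2 fold change 5.70 ± 0.11 SE, adjusted p = 1.49e-07). AT2G23270, which encodes an uncharacterized protein, rose 104-fold, from 0.493 ± 0.0715 to 51.0 ± 11.3 TPM. CYP71A12, a cytochrome P450 of the camalexin and indole carbonyl nitrile routes, rose 36.8-fold, from 6.44 ± 5.04 to 237 ± 66.0 TPM, and 66.2-fold without control replicate 1. AT1G26240, an extensin-like gene, rose 63.5-fold, from 0.559 ± 0.266 to 35.5 ± 15.6 TPM. AT3G23122, whose annotated coding sequence is only 18 bases long, had 0.205, 0, 0 TPM in the control libraries and 11.6, 19.0, 22.7 TPM in the DMMTA libraries. Among the largest falls, EXT13, an extensin-like cell wall protein, went from 30.9 ± 8.70 to 0.619 ± 0.217 TPM, and AGP30, an arabinogalactan protein, from 63.4 ± 13.6 to 3.91 ± 1.58 TPM. GSTF14, a phi class glutathione S-transferase, fell 19.5-fold, from 134 ± 69.0 to 6.86 ± 1.14 TPM. The peroxidase gene AT2G39040 had 8.35, 7.81, 9.12 TPM in the control libraries and 0.0633, 0.205, 0.0532 TPM in the DMMTA libraries. AT5G46900, of the lipid transfer protein family, had 28.0, 13.1, 21.8 TPM in the control libraries and 0.208, 0, 0.417 TPM in the DMMTA libraries.

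All 10 tested members of the DNA damage response list rose, with a median log2 fold change of 2.72. Beside SMR7, its largest change was in SMR5 (AT1G07500), another SIAMESE-RELATED inhibitor, from 1.12 ± 0.559 to 45.5 ± 2.78 TPM. The list was called higher by camera (adjusted p = 1.65e-12 at a preset inter-gene correlation of 0.01, and adjusted p = 0.122 with an estimated correlation). In the cell division list 5 members rose and 3 fell of 9, and it was not called (adjusted p = 0.377). TSO2, the small subunit of ribonucleotide reductase, rose 6.37-fold, from 53.7 ± 0.164 to 342 ± 29.6 TPM, and MCM5, a subunit of the replicative helicase, rose 1.66-fold. KN, the cytokinesis syntaxin (annotated SYP111), fell from 20.2 ± 4.47 to 9.60 ± 4.68 TPM, a call that was lost without control replicate 1 (adjusted p = 0.0528), control replicate 3 (0.0865), DMMTA replicate 2 (0.0807), DMMTA replicate 3 (0.0853) or both replicate 3 libraries (0.208).

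Genes for the handling of foreign compounds rose as a group. All 20 tested members of the xenobiotic detoxification list rose, with a median log2 fold change of 1.76 (camera adjusted p = 1.51e-13, and adjusted p = 0.122 with an estimated correlation). UGT73B4, a UDP-glycosyltransferase, went from 3.78 ± 0.744 to 55.6 ± 3.19 TPM, and CYP81D8, a cytochrome P450, from 4.06 ± 0.872 to 45.7 ± 1.22 TPM. Of 37 glutathione S-transferases, 22 rose and 7 fell (camera adjusted p = 3.99e-04, and adjusted p = 0.349 with an estimated correlation). The tau class genes GSTU25 and GSTU24 rose 19.1-fold and 17.1-fold, from 13.9 ± 1.64 to 265 ± 18.9 TPM and from 13.7 ± 3.51 to 235 ± 2.50 TPM, and GSTF14 was the largest fall. All 12 members of the list of oxidative stress regulators rose (median 2.22, camera adjusted p = 1.39e-10, and adjusted p = 0.188 with an estimated correlation). Its largest changes were in WRKY75, 7.77-fold, and in OXI1, 7.93-fold, which encodes a protein kinase and not a transcription factor.

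Genes of glutathione and phytochelatin synthesis rose by less than 2-fold where they passed the test. GSH1, the first enzyme of glutathione synthesis, rose from 286 ± 41.9 to 432 ± 23.9 TPM (log2 fold change 0.61 ± 0.12 SE, adjusted p = 0.00581), a call that did not hold without both replicate 3 libraries (adjusted p = 0.0663). GSH2, the second enzyme, rose 1.77-fold, from 103 ± 13.1 to 182 ± 5.07 TPM. PCS1, the main phytochelatin synthase (annotated CAD1), rose 1.75-fold, from 72.2 ± 10.8 to 126 ± 8.34 TPM, whereas PCS2 was at 1.36 ± 0.226 TPM in control and 1.26 ± 0.374 TPM in DMMTA (adjusted p = 0.762). ABCC2, a vacuolar transporter of phytochelatin complexes, rose 2.09-fold, from 13.1 ± 3.60 to 27.3 ± 0.738 TPM. Its relative ABCC1 was at 28.1 ± 9.97 TPM in control and 36.8 ± 4.17 TPM in DMMTA and did not pass the test (adjusted p = 0.223). HAC1 (AT2G21045), an arsenate reductase, fell from 165 ± 47.5 to 103 ± 11.9 TPM (adjusted p = 0.0409), and the call was lost with no expression filter (adjusted p = 0.0678), without control replicate 1 (0.0874), without control replicate 3 (0.101), without each DMMTA library in turn (0.0624 to 0.122) and without both replicate 3 libraries (0.140). The largest changes of the whole list were in WRKY45, 7.10-fold up, and WRKY6, 3.19-fold up, transcription factors that regulate phosphate transporters. With 6 members up and 2 down of 12, this list was not called (camera adjusted p = 0.139). Most of the NIP channel genes among its 18 written members had no usable value. Sulfate uptake and assimilation was not called either (4 up and 1 down of 12, adjusted p = 0.829), with the ATP sulfurylase APS1 up 1.75-fold, the APS reductase APR3 up 1.55-fold and APS4 down 1.52-fold. Most of the sulfate transporters among its 22 written members had no usable value, so the result bears mainly on assimilation. Sulfur starvation markers gave 1 up and 1 down of 8 (adjusted p = 0.839), and the sulfate transporters among the 12 written had no usable value. SDI1, which fell 2.02-fold, lost its call without both replicate 3 libraries (adjusted p = 0.0530).

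**Figure D2:**
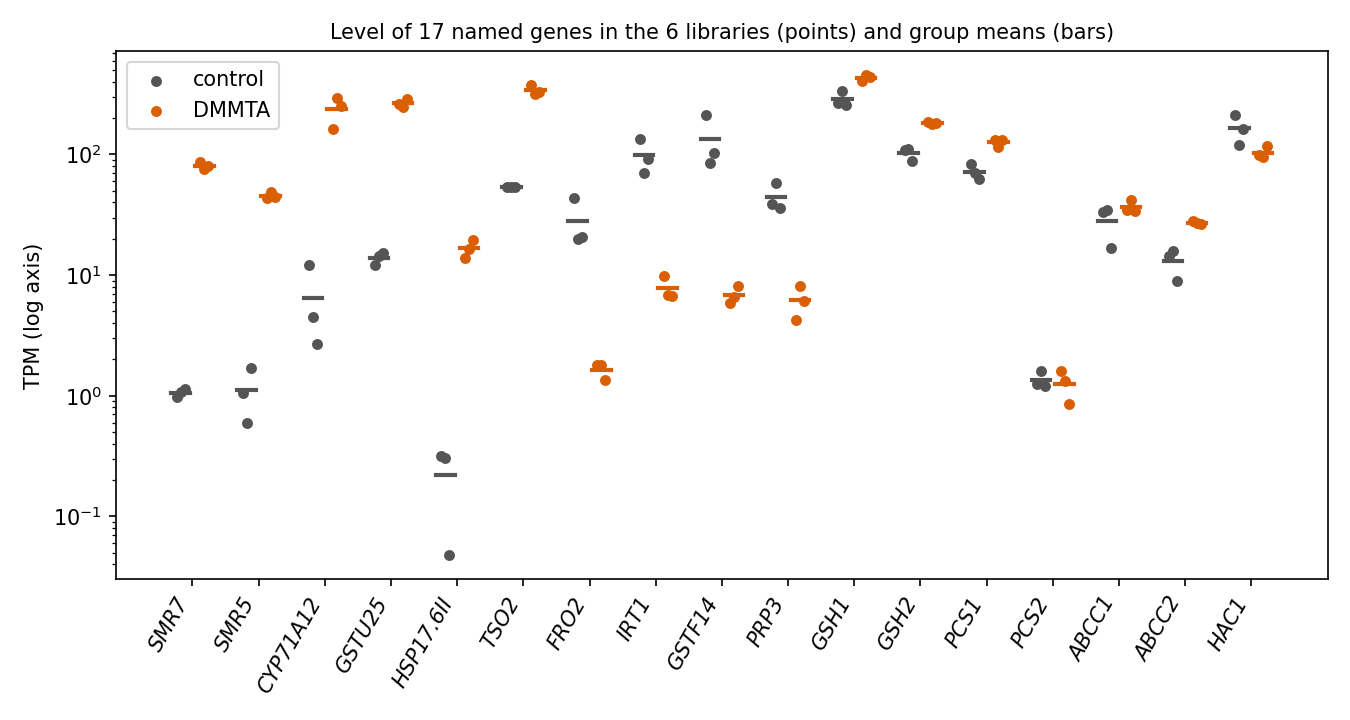
TPM on a log axis of 17 named genes in each of the 6 libraries (points, grey for control and orange for DMMTA) with group means (bars). SMR7 lies near 1.06 TPM in control and 80.5 TPM in DMMTA, while PCS2 and ABCC1 overlap between the groups.

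In the heat shock list 18 of 22 members rose and none fell (median log2 fold change 1.93, camera adjusted p = 5.37e-13, and adjusted p = 0.188 with an estimated correlation). That median was 1.22 without DMMTA replicate 1 and 1.24 without both replicate 3 libraries. The small heat shock proteins HSP17.6II and HSP17.6A rose 75.2-fold and 45.9-fold, HSP17.6II from 0.223 ± 0.152 to 16.7 ± 2.88 TPM. The 26S proteasome list had 11 of 23 members up and none down, by a small amount (median 0.29, camera adjusted p = 6.48e-05, and adjusted p = 0.564 with an estimated correlation). RPN6 (annotated ATS9) rose 1.76-fold and RPN10, a ubiquitin receptor, 1.43-fold. Of the unfolded protein response list of the endoplasmic reticulum, 5 of 18 rose and 1 fell (adjusted p = 0.416), and whether the lists differ was not tested. NAC103 rose from 0.815 ± 0.274 to 4.60 ± 0.711 TPM and BZIP60, a stress-activated transcription factor, 2.02-fold, while the calreticulin gene CRT1b fell 1.32-fold. The mitochondrial dysfunction list, genes induced when mitochondria are impaired, had 8 of 10 up and 1 down (camera adjusted p = 9.43e-05, and adjusted p = 0.341 with an estimated correlation). BCS1 rose 4.67-fold and NDB2, an external NADH dehydrogenase, 4.56-fold, whereas NDB4 fell 2.02-fold. Antioxidant enzymes went both ways, 9 up and 4 down of 27 (adjusted p = 0.94). Glutathione reductase GR1 rose 2.41-fold, GPX6 1.88-fold, and DHAR1 fell 1.47-fold.

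Genes of iron uptake fell. Of 16 tested members of the iron deficiency list, 10 fell and 1 rose (median log2 fold change -1.03, camera adjusted p = 1.94e-07, and adjusted p = 0.341 with an estimated correlation). That median was -0.65 with the stricter expression filter. FRO2, the root ferric chelate reductase, fell 17.1-fold, from 28.1 ± 13.3 to 1.64 ± 0.256 TPM, and IRT1, the main iron importer, 12.7-fold, from 99.0 ± 33.4 to 7.82 ± 1.79 TPM. BTS, a negative regulator of iron uptake, rose 1.82-fold. In the list of iron storage and metallothionein genes 4 of 9 fell and 1 rose (adjusted p = 0.00986, and adjusted p = 0.487 with an estimated correlation). The metallothionein MT1C fell 3.53-fold and ferritin FER1 2.11-fold, while FER2 rose 1.42-fold. Root hair markers fell in the same libraries, 8 of 8, with a median of -1.52 (adjusted p = 8.45e-08, and adjusted p = 0.188 with an estimated correlation). The cell wall gene PRP3 went from 44.4 ± 12.2 to 6.18 ± 1.96 TPM and RHS13 from 59.9 ± 2.63 to 13.4 ± 2.38 TPM. Root endodermis markers divided into 6 that rose and 4 that fell of 11 (adjusted p = 0.416). The suberin genes FAR5 and CYP86B1 each rose 3.82-fold, and CASP1, of the Casparian strip, fell 3.85-fold, from 47.4 ± 1.04 to 12.3 ± 7.34 TPM, with adjusted p = 0.0598 without both replicate 3 libraries.

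The salicylic acid and camalexin list had 9 of 13 members up and none down (adjusted p = 7.06e-04, and adjusted p = 0.564 with an estimated correlation), led by CYP71A12 and by PAD3, the last enzyme of camalexin synthesis, from 29.4 ± 12.0 to 231 ± 14.9 TPM. The flavonoid list had 10 up and 1 down of 19 (adjusted p = 2.06e-04, and adjusted p = 0.487 with an estimated correlation). The flavanone hydroxylase F3H rose from 16.1 ± 2.75 to 147 ± 28.7 TPM and the flavonol regulator MYB12 6.96-fold, while its relative MYB111 fell 1.69-fold. Ethylene genes had 6 of 13 up and none down (adjusted p = 0.0201, and adjusted p = 0.564 with an estimated correlation), with the ACC synthases ACS2 and ACS6 up 6.02-fold and 4.30-fold. That call did not hold with a stricter expression filter (adjusted p = 0.128), without control replicate 3 (adjusted p = 0.0536) or without both replicate 3 libraries (adjusted p = 0.0501). Glucosinolate genes moved in both directions, 8 up and 10 down of 22 (adjusted p = 0.213). MAM3 (annotated IMS2), which elongates methionine side chains, fell 4.24-fold and MYB34, a regulator of indolic glucosinolates, 3.21-fold, whereas CYP81F2, which modifies indolic glucosinolates, rose from 8.94 ± 3.07 to 123 ± 24.3 TPM.

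The remaining lists were not called. Photosynthesis genes had 35 of 38 members not past the test (median -0.03, camera adjusted p = 0.416), with RBCS1B down 1.51-fold, RCA down 1.31-fold and LHCB2.1 up 1.41-fold. Chlorophyll synthesis had 10 of 11 not past it (adjusted p = 0.695), CHLD (annotated ALB1) being at 68.5 ± 1.54 TPM in control and 57.3 ± 1.00 TPM in DMMTA. Jasmonate genes gave 3 up and 1 down of 22 (adjusted p = 0.976), with CYP94B3, which inactivates the hormone, up 12.6-fold, LOX4 up 2.44-fold and JAZ3 down 1.74-fold. Abscisic acid genes gave 4 up and 1 down of 14 (adjusted p = 0.416), COR47 rising 1.80-fold, RD26 1.63-fold and P5CS1 falling 1.67-fold. Phosphate starvation genes gave 5 up and 1 down of 14 (adjusted p = 0.213, and 0.0266 without DMMTA replicate 2), with MGDC up 2.89-fold, PAP17 up 2.39-fold and PPCK1 down 1.46-fold. None of the PHT1 phosphate transporters among the 24 written members had a usable value. In the auxin list 1 of 9 rose, IAA5 by 1.64-fold (adjusted p = 0.829). In the circadian list 3 of 9 rose (adjusted p = 0.0744, and 0.0392 without control replicate 3 and 0.0219 without both replicate 3 libraries), with PRR9 up 2.79-fold and PRR5 up 1.61-fold. None of the 10 matched seed storage genes passed the expression filter. The calls of CRT1b, DHAR1, FER2, MYB111, RBCS1B, RCA, LHCB2.1, CHLD, JAZ3, P5CS1, PPCK1 and IAA5 were each lost in at least 1 of the fits that leave out a library. Adjusted over the list alone, the counts up and down were 23 and 9 for glutathione S-transferases, 16 and 0 for the proteasome, 9 and 9 for antioxidant enzymes, 1 and 12 for iron deficiency, 1 and 5 for iron storage and 8 and 12 for glucosinolates. They were 4 and 2 for sulfate assimilation, 6 and 3 for glutathione and arsenic handling, 7 and 1 for phosphate, 8 and 1 for ethylene, 9 and 1 for salicylic acid and camalexin and 6 and 3 for cell division. Photosynthesis, chlorophyll synthesis and auxin each had 0 and 0, and the other lists had the counts given over all genes. The mean differed in sign from the median and the test for antioxidant enzymes (mean 0.07), jasmonate (mean 0.14) and glucosinolates (mean 0.02), and for chlorophyll synthesis the mean and median were both just above 0 while the test pointed down.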

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

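The alternatives with median-of-ratios scaling, limma-voom, pseudocounts, FPKM, nuclear loci, members of unknown symbol and the loss of both replicate 3 libraries were chosen after seeing the data, the others before. Main counts were 3273 genes higher and 1979 lower, with 10 lists higher and 3 lower. Leaving out each library gave 2076 to 3138 higher and 1132 to 1577 lower, with 10 to 11 lists higher and 3 lower. The lowest counts came without DMMTA replicate 3 (2076 and 1132), and without DMMTA replicate 2 the number higher was 2181. Without both replicate 3 libraries the counts were 1843 and 847, from fewer samples. Requiring at least 2-fold, by the log2 fold change, gave 1165 and 610. An adjusted p under 0.01 gave 1989 and 923, and both settings are stricter by construction. Other filters, pseudocounts, FPKM and nuclear loci gave 2857 to 3401 higher and 1446 to 2035 lower. Median-of-ratios scaling gave 3111 and 2353 (56.9% of calls higher) and limma-voom 2828 and 2737 (50.8%, against 62.3%). The median log2 fold change of all genes moved the same way, from 0.04 in the main fit to -0.004 and -0.05. The excess of calls higher therefore depends on how the libraries are scaled and fitted, and which choice is right was not tested. In each fit with other libraries, filters or scalings, no main call was called in the opposite direction. With an estimated correlation 0 lists were called higher and 0 lower by camera, the lowest adjusted p being 0.122, while fry, which tests each list's own genes, called 15 higher and 3 lower. Fry called the antioxidant enzymes higher (adjusted p = 0.0142). Their median was -0.0911, but their mean was 0.0675, and 9 rose while 4 fell, on the side of the fry call. Whether the mean accounts for that call was not tested. Whether the replicate numbers pair the samples stays open, since the labels do not say what a number marks. Same-numbered libraries deviated together with correlations of 0.243, 0.334 and 0.082 across genes, each library correlating best with its own number. That is a hint from the data only, and 0.082 is below the bound fixed beforehand for every pair. The replicate block gave 3539 higher and 2242 lower, with 10 lists higher and 4 lower, the added one being glucosinolate synthesis (adjusted p = 0.0386). Among named genes 1192 values under alternatives kept their call or lack of one, 73 lost the call and 0 reversed. DESeq2's Wald test and its size factors passed to edgeR were not run, because they need counts, and library totals alone are what the main values already use. Depth limits the lowest genes. The simulation recovered 16.7% of genes changed 1.5-fold, but from 200 seeded genes and with 116 calls, against 5252 real calls. The adjusted p is stricter where fewer genes change, so the share of small changes missed in the real comparison was not measured.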

Other observations

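Gene families taken from the annotation's product descriptions, fixed before the data were examined, showed changes too, though some share members with the lists above. Of the expansins, 12 of 23 fell and none rose (median log2 fold change -0.87, camera adjusted p = 5.54e-08, and adjusted p = 0.108 with an estimated correlation). EXPA7 and EXPA18 among them are also root hair markers, a list of which 8 of 8 fell in the same libraries (median -1.52), and CASP1 to CASP4 of the endodermis list had a median of -1.73. Of 9 aquaporins tested, 8 fell (median -0.98, adjusted p = 5.92e-08, and 0.267 with an estimated correlation), PIP2B from a mean of 241 to 45.3 TPM and PIP1A from 244 to 47.9 TPM. The descriptions matched only 10 genes, and several aquaporins, NIP channels among them, had no usable value, so this is only a part of the family. Of 59 SAUR genes, a family that responds to auxin, 20 fell and none rose (adjusted p = 2.00e-06, and 0.572 with an estimated correlation). Xyloglucan endotransglucosylases, which remodel the cell wall, gave 8 down and 3 up of 22 (adjusted p = 0.0038, and 0.396 with an estimated correlation), with XTH12 from 15.1 to 0.801 TPM. Genes described as members of the peroxidase superfamily gave 20 down and 14 up of 54 (adjusted p = 0.0116, and 0.572 with an estimated correlation), and those up include DOX1, an alpha-dioxygenase and not a class III peroxidase. A set meant for cytosolic ribosomal proteins, whose descriptions also match organellar and elongation factor-like genes such as RFC3 and AT3G12915, was called lower with a small median of -0.18 (15 down and 3 up of 177, adjusted p = 7.53e-08, and 0.572 with an estimated correlation). The medians of these 6 families were negative under all 4 other scalings and columns tried. But these moved the median of all genes only from 0.04 to -0.05, too little to turn the family medians positive, so they decide nothing.

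Of 34 cysteine-rich receptor-like kinases, 18 rose and none fell (median 0.76, adjusted p = 7.88e-06, and 0.572 with an estimated correlation). WRKY transcription factors gave 26 up and 4 down of 58 (adjusted p = 2.54e-04, and 0.572 with an estimated correlation). UDP-glycosyltransferases gave 37 up and 12 down of 105 (adjusted p = 0.0038, and 0.572 with an estimated correlation), and MATE efflux transporters 17 up and 5 down of 40 (adjusted p = 0.0178, and 0.596 with an estimated correlation). Some members, such as WRKY75, UGT73B4 and the MATE gene DTX1, also belong to the lists above, so these rises are not independent of them. Core histones are given below, and the other 7 families were not called, with adjusted p from 0.0880 to 0.930. They include cytochromes P450 (31 up and 30 down of 147), the ethylene response factor family (11 up and 10 down of 51), ABC transporters and glutaredoxins. Genes whose descriptions matched thioredoxins gave 9 up and 8 down of 85 (adjusted p = 0.363). Among them AT5G18600 had a log2 fold change of -3.46 and AT4G15700 went from a mean of 7.38 to 1.40 TPM, 2 genes singled out after their values were seen. Both were placed by description only, and whether they are thioredoxins or glutaredoxins was not checked.

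All the tests that follow were chosen after the results they bear on were seen, and the bound for the core histones was made stricter after their median was known. The real grouping gave 5252 calls and the highest of the other 9 groupings of the 6 libraries gave 0 in limma. With 10 groupings, 1 of which is the real one, the share cannot go under 0.1, which is too few for a test.

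The fall of the root hair markers (median -1.52, SD 0.63 over 8 genes) was set against 3 technical explanations. A lower share of root RNA would lower the endodermis list by about as much. Its median was 0.81 (SD 1.68 over its members), and at its lowest over the alternatives, with no expression filter, 0.36 (SD 1.61). But the list was divided, with CASP1 to CASP4 down and its 7 suberin genes up. Its median therefore cannot gauge the share of root RNA, and this explanation stays open. Removing the trend of fold change on coding length and GC content left the root hair median at -1.57. Less RNA from the young part of the root also stays open, since CASP1 to CASP4, singled out after their values were seen, had a median of -1.73 while the 7 suberin genes of the same list had one of 1.70. An effect of DMMTA on transcription in these cells was not tested and stays open too.

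The rise of the DNA damage list (median 2.72) kept a median of 2.68 after the same trend was removed, which argues against coding length or GC content. Its lowest median over the scalings tried was 2.67, but these moved the median of all genes only from 0.04 to -0.05, so they could not have brought the list near 0 and decide nothing. An effect of DMMTA, the difference the design names, was not tested apart from the comparison itself, and no measurement of DNA damage was analysed here.

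In the cell division list the replication genes PCNA1, PCNA2, MCM2, MCM5, PRL and TSO2 had a median log2 fold change of 0.60 (SD 0.89), and the mitotic genes CYC1BAT, CDC20.1 and KN one of -1.08, a division of the list made after its values were seen. The mitotic median rests on 3 of 11 written members, since the others had no usable value, and KN lost its call in 5 of the fits that leave out libraries. A lower share of dividing cells therefore stays open. The fall of core histones goes with it, and the replication genes, of which 5 of 6 rose and PCNA1 did not pass (adjusted p = 0.110), go against it. Their median lies within its SD of no change, but above the mitotic median by more than that SD. A larger share of cells in S phase would raise the core histones, of which 16 of 45 fell and 5 rose (camera adjusted p = 9.69e-05, and 0.572 with an estimated correlation). That set also held histone-modifying enzymes, and without them 16 of 40 fell and 3 rose (median -0.27, SD 0.42). The rise was not seen, which goes against a larger S phase share. But the median lies within its SD of no change, under a bound made stricter after it was known, so that explanation is not settled.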
